A study of Homo sapiens with 12 samples.

How the data were processed

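Gene expression was measured by RNA sequencing in 12 libraries from human lymphoma cell lines, OCI-LY3 and SU-DHL6, grown untreated or with selinexor. Per the labels' protocols, RNA was isolated with a spin-column kit and 1.3 µg of it entered an mRNA library kit. Per the labels' titles, each of the 4 groups holds 3 libraries, and the design text calls them biological triplicates without saying how the cultures were set up. The protocols name 300 and 100 nM selinexor and 24 and 48 h of treatment, but no label ties a dose or a time to a library or to a line. Dose and time may therefore differ between the lines, and no value here is assigned to a dose or a time.

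The table the authors deposited gives a read count and an FPKM value for each of 58302 genes in each library, per the file headers, and every one of its columns of values was mapped to a library by name. The aligner, the counting program and its strand setting are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10, whereas the identifiers in the table are human Ensembl identifiers. Of these, 58039 were found in GENCODE release 29 on GRCh38, and 97.5% of the matched ones had identical coordinates, so coordinates below are those of the table on GRCh38. The other 263 identifiers carry no gene type. The deposited FPKM values were checked against the counts over 9162 genes with at least 50 counts: each gene's implied length differed between libraries by a ratio of at most 1.000019, so they hold no further information and were not tested. No row named anything other than a gene.

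The deposited counts are whole numbers, but 235 genes, 126 of them microRNA genes, had a count of exactly 1 in all 12 libraries, where Poisson counting would give 0.0187 such genes. Counts may thus be rounded estimates in part. Some genes differed severalfold between replicates of a group while most did not: between 223 and 364 of the 8711 to 9291 genes with at least 10 CPM (counts relative to the library total) in a group exceeded a 2-fold range. Genes that overlap another gene, ribosomal protein genes with pseudogenes, histone genes and other near-identical families are uncertain for the same reason, since the handling of shared reads is not stated. Of the genes fixed for both lines, BCL6 and MCL1 overlap another gene, as do ASNS and RN7SL2.

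Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 16474 genes, libraries were scaled with TMM factors, and 1 negative binomial model with a coefficient per group was fitted to all 12 libraries. The quasi-likelihood F test with robust dispersion moderation was used for each contrast, with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Standard errors (SE) are the log2 fold change divided by the square root of F. Rose, fell, higher and lower are used of genes past this threshold. CPM values are relative to the TMM-scaled library totals and given as mean ± SD over 3 libraries. The contrasts were selinexor against untreated in each line, the difference of these responses (SU-DHL6 minus OCI-LY3), and untreated OCI-LY3 against untreated SU-DHL6.

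A total of 33 gene lists were fixed before the data were examined. Lists with at least 5 tested members were tested in each line with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of both lines. The same test with a correlation estimated from the data, and fry, were alternatives. Counts of members are given over all genes tested and adjusted over the list alone. Named genes followed a rule fixed at the same time. For each line, it took the 8 largest rises and 8 largest falls among called protein or RNA genes with a mean log2 CPM of at least 3 in that line and no overlap between treated and untreated libraries. It added up to 2 members per direction of each list with the smallest adjusted p, the 5 largest per direction for the other contrasts (for the difference, with no such overlap in at least 1 line), XPO1, and MYC, BCL2, MCL1, BCL6, CDKN1A, NFKBIA, IRF4 and PRDM1 in each line. The text names only part of the list members that the rule selected, which were picked for it after their values were seen, and some genes are not reported here. Clone-based names and pseudogenes were left out. A value given in the other line for a gene so chosen, and the levels of a gene in the untreated lines, come from the same fits.

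Alternatives fixed before the data were examined were other size factors, DESeq2 1.42.0, limma-voom, other filters and thresholds, each line alone, the replicate number as a block, and leaving out each library in turn. A further 4 settings, scaling by total counts, offsets per library for GC content and gene length, and fits without overlapping genes or without the genes that differed over 2-fold between replicates, were chosen after seeing the data. The test was tried on simulated counts drawn from the means and library sizes of these data with 200 genes changed per line. For a 2-fold change, over 16089 tested genes, it recovered 75% of the changed genes in the OCI-LY3 comparison, 77.5% in the SU-DHL6 comparison and 42.9% of 394 in the difference between the lines, with 6.25%, 6.63% and 6.63% false calls. For a 1.5-fold change, over 16094 genes, it recovered 9%, 14.5% and 1.53%, with 0%, 17.1% and 40% false calls among 18, 35 and 10 genes called. Small changes were thus mostly missed in that setting. In the data far more genes were called, 7321 in OCI-LY3, which loosens the adjusted threshold. The simulated shares therefore do not carry over to the data. In a simulation with 1 list changed 1.5-fold, over 16124 genes, camera called that list and 0 others of 64 list tests. Table handling used Python 3.11.15.

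Library totals ranged from 14210200 to 16405842 counts, so a floor of 3 counts per library corresponds to 0.183 to 0.211 CPM before TMM scaling. A fold against a group with 0 counts is given as a lower bound from that floor. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 11.5 to 29.6), and each library was counted as its own replicate.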

Results

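RNA sequencing was used to ask how diffuse large B-cell lymphoma lines change their gene expression under selinexor, a drug that binds the nuclear export receptor XPO1 and blocks export of its cargo from the nucleus. OCI-LY3 is an established line that the labels assign to the activated B-cell type of this lymphoma, and SU-DHL6 is an established line that they assign to the germinal centre B-cell type. Each of the 4 groups (untreated and selinexor-treated cells of each line) had 3 libraries, and library totals ranged from 14210200 to 16405842 counts. Replicates of a group correlated at 0.981 to 0.986 over log2 CPM. The first principal component held 79.7% of the variance and separated the lines, and the second (8.41%) separated treated from untreated libraries in both lines. The third (4.91%) also separated them, in opposite directions in the lines. The first untreated SU-DHL6 library stood apart on the fourth component (1.21% of the variance) with a score of -41.5, against 16.2 and 17.5 for its replicates, as did the third treated OCI-LY3 library (-25.0, against 12.6 and 8.29).

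XPO1 mRNA, the transcript of the drug's target, rose in both lines. XPO1 (ENSG00000082898, chromosome 2, 61477849 to 61538626 on GRCh38) was at 179 ± 7.8 CPM in untreated and 355 ± 24.5 CPM in treated OCI-LY3 (SD, n = 3 per group), a log2 fold change of 0.99 ± 0.13 (SE). In SU-DHL6 it was at 153 ± 23.5 CPM untreated and 520 ± 76.6 CPM treated, a log2 fold change of 1.77 ± 0.13. In each line, the lowest treated library lay above the highest untreated library: 329 against 186 CPM in OCI-LY3, and 434 against 179 CPM in SU-DHL6. The rise was larger in SU-DHL6 by 0.78 ± 0.18 on the log2 scale (edgeR quasi-likelihood test of the difference, Benjamini-Hochberg adjusted p = 0.00325).

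**Figure D1:**
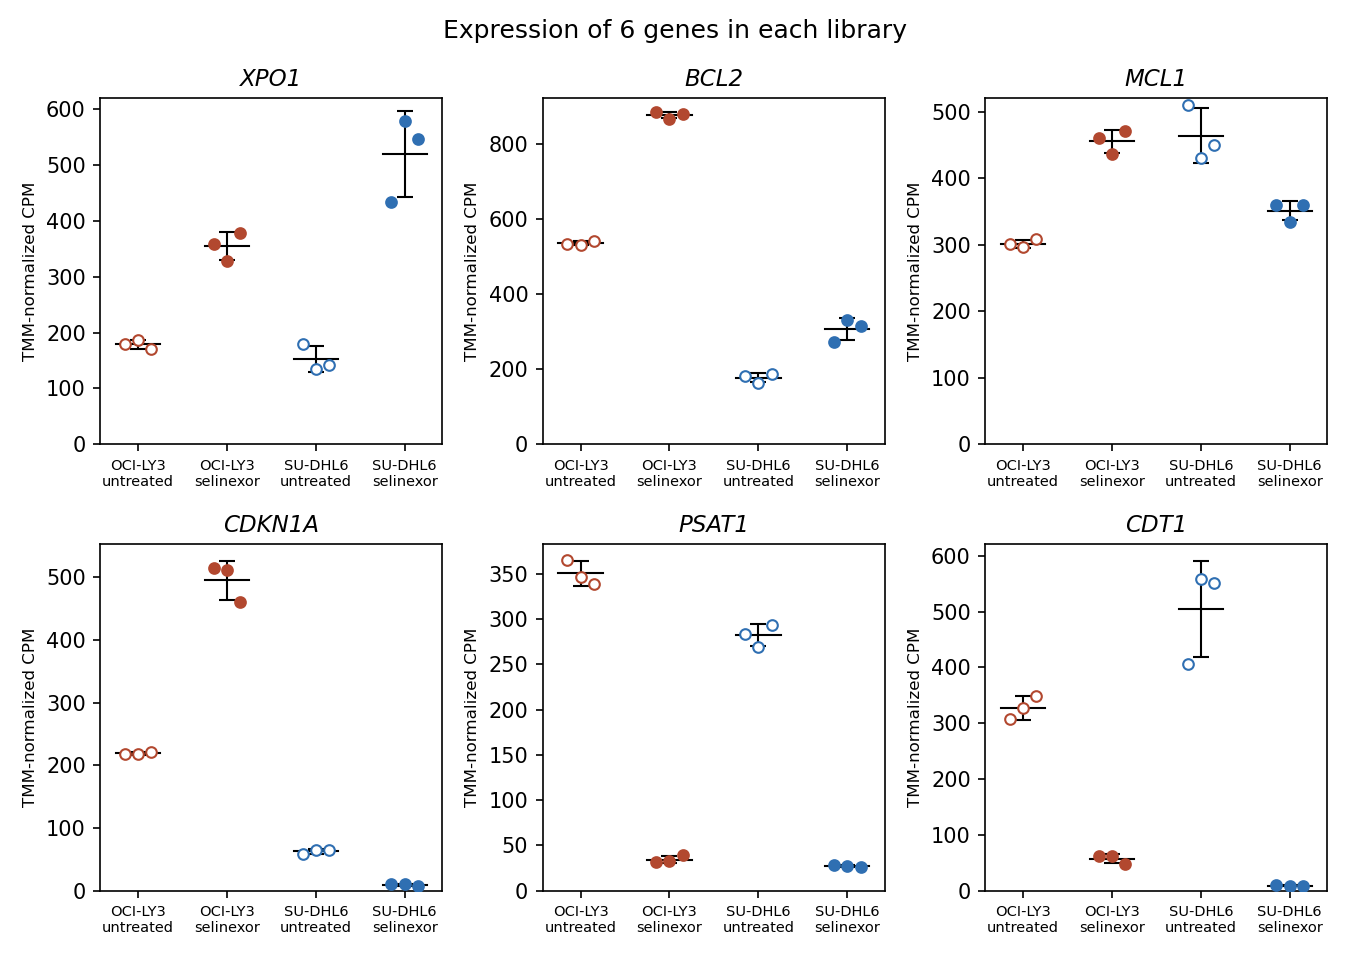
TMM-scaled CPM of 6 genes in each library (vertical axes start at 0). Open points are untreated and filled points selinexor-treated libraries, red for OCI-LY3 and blue for SU-DHL6, and bars give the mean ± SD of 3 libraries; XPO1 and BCL2 rose and PSAT1 and CDT1 fell in both lines, while CDKN1A and MCL1 rose in OCI-LY3 and fell in SU-DHL6, where scaling by total counts ended the MCL1 call.

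In OCI-LY3, the largest rises among the called genes with a mean log2 CPM of at least 3 in that line and no overlap between treated and untreated libraries began with CXCL13. CXCL13 (ENSG00000156234, chromosome 4, 77511753 to 77611834), a B cell-attracting chemokine, went from 0.735 ± 0.284 to 132 ± 14.8 CPM (SD, n = 3), a log2 fold change of 7.47 ± 0.23 (SE). The neurotrophin receptor gene NGFR rose by 6.35 ± 0.22, TRIM22 by 4.37 ± 0.13, the actin-severing protein gene GSN by 4.20 ± 0.12 and CD180, a Toll-like receptor relative of B cells, by 4.10 ± 0.13. KCNJ11, a potassium channel subunit, rose by 4.08 ± 0.48, PHLDA1 by 3.80 ± 0.41 and FXYD2, which overlaps another gene, by 3.53 ± 0.11. The largest falls among genes that met the naming rule were those of CTH (-4.18 ± 0.21), which makes cysteine, the transcription factor gene ETV4 (-4.03 ± 0.24), the metallothionein genes MT1E (-4.00 ± 0.21) and MT2A (-3.40 ± 0.14), and PXDN (-3.85 ± 0.18). GPT2 (-3.77 ± 0.29) and ASNS (-3.55 ± 0.23), which make alanine and asparagine, and the kinetochore gene SKA1 (-3.54 ± 0.39) followed.

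Most genes of the proliferation lists fell in treated OCI-LY3. Of 48 DNA replication and E2F target genes, 46 fell and 0 rose (the same adjusted over the list alone), with a median log2 fold change of -1.40. CDT1 (-2.52 ± 0.14) and ORC1 (-2.47 ± 0.10), which license replication origins, were among them. Of 48 mitosis genes, 46 fell and 0 rose (the same adjusted over the list alone), among them KIF2C (-2.17 ± 0.10) and TPX2 (-1.92 ± 0.08). Both lists were called by camera (adjusted p = 2.3e-25 and 1.8e-25, and 0.0003 and 0.0137 with an estimated correlation). DNA repair genes fell in 31 of 41 and rose in 2 (the same adjusted over the list alone), with RAD54L at -2.06 ± 0.11 and EXO1 at -1.85 ± 0.12. For this list, camera gave an adjusted p of 1.1e-09, and 0.0784 with an estimated correlation. Transcripts of replication histones moved the other way: 16 of 23 measured genes rose and 1 fell (the same adjusted over the list alone), with HIST1H2BD at 3.02 ± 0.17 and HIST1H4H at 2.57 ± 0.21. For replication histones, camera gave an adjusted p of 2.1e-05, and 0.00765 with an estimated correlation. Histone genes are near-identical copies whose reads the counting could split. Only 23 of the 41 listed histone genes were measured, in libraries made with an mRNA kit. In either line, these counts may therefore not stand for all histone transcripts.

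Genes induced by ATF4, the transcription factor of the amino acid stress response, fell in 31 of 33 cases and rose in 0 (32 and 0 adjusted over the list alone). The serine synthesis gene PSAT1 (-3.35 ± 0.10) and AARS, an alanyl-tRNA synthetase gene (-2.25 ± 0.08), were among them. For ATF4 targets, camera gave an adjusted p of 2.0e-20, and 0.00242 with an estimated correlation. NRF2 target genes fell in 12 of 18 cases and rose in 1 (the same adjusted over the list alone), with HMOX1 at -2.29 ± 0.10 and SRXN1 at -1.93 ± 0.12. For NRF2 targets, camera gave an adjusted p of 0.000121, and 0.0283 with an estimated correlation. Fatty acid synthesis genes fell in 11 of 14 cases and rose in 1 (the same adjusted over the list alone), with ELOVL5 at -1.26 ± 0.09 and ACACA at -1.06 ± 0.10. Cholesterol synthesis genes rose in 12 of 25 cases and fell in 2 (13 and 2 adjusted over the list alone), with LSS at 1.24 ± 0.12 and MSMO1 at 1.03 ± 0.10. The camera adjusted p was 0.000146 for fatty acid and 0.00307 for cholesterol synthesis, and 0.0140 and 0.0308 with an estimated correlation. Glycolysis and hypoxia genes fell in 15 of 31 cases and rose in 2 (15 and 3 adjusted over the list alone), with HK2 at -2.04 ± 0.09 and PFKFB4 at -1.63 ± 0.09. For glycolysis and hypoxia, camera gave an adjusted p of 0.000373, and 0.0588 with an estimated correlation. Genes of the endoplasmic reticulum list (chaperones and the unfolded protein response) fell in 14 of 28 cases and rose in 5. Counts adjusted over the list alone were the same, with SEC24D at -1.89 ± 0.12 and EDEM1 at -1.22 ± 0.10 among the falls. For this list, camera gave an adjusted p of 0.0137, and 0.108 with an estimated correlation.

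p53 target genes rose in 28 of 37 cases and fell in 2 (the same adjusted over the list alone), with a median log2 fold change of 0.89. TRIM22 (4.37 ± 0.13) and RPS27L (2.31 ± 0.11) had the smallest adjusted p among those that rose, and the cell cycle inhibitor gene CDKN1A rose by 1.18 ± 0.11. The members that fell were SESN2 (-2.34 ± 0.14) and GDF15, which are also known ATF4 targets; GDF15 went from 0.875 CPM to 0 counts, at least 3.83-fold lower. The list was called by camera (adjusted p = 3.3e-10, and 0.00124 with an estimated correlation). In the BCL2 family and apoptosis list 11 of 27 genes rose and 4 fell (the same adjusted over the list alone), with the pro-apoptotic BAX at 1.83 ± 0.12 and the anti-apoptotic BCL2L1 at 1.24 ± 0.11. For apoptosis, camera gave an adjusted p of 0.0174, and 0.0572 with an estimated correlation, and the median of 0.29 became 0.17 with total counts and 0.60 without the genes that differed over 2-fold between replicates. Cytosolic ribosomal protein genes rose in 42 of 61 cases and fell in 0 (43 and 0 adjusted over the list alone), with a median of 0.57, and the share of counts on pseudogenes went from 6.59 to 6.86% in untreated to 8.16 to 8.45% in treated libraries. RPL22 rose by 0.94 ± 0.10, but the list's call (camera adjusted p = 3.3e-10) was lost with an estimated correlation (adjusted p = 0.262). Ribosome biogenesis genes fell in 26 of 43 cases and rose in 2 (29 and 2 adjusted over the list alone), with DDX21 at -1.13 ± 0.12 and NOP58 at -0.71 ± 0.10. For ribosome biogenesis, camera gave an adjusted p of 2.7e-06, and 0.00765 with an estimated correlation.

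Nuclear transport genes mostly fell in OCI-LY3: 22 of 40 members of the list fell and 4 rose (22 and 5 adjusted over the list alone). The tRNA exporter gene XPOT (-1.42 ± 0.10) and XPO5 (-1.11 ± 0.08), which encodes the microRNA precursor exporter and overlaps another gene, fell, while RANBP3, an XPO1 cofactor gene, rose by 0.86 ± 0.10. For nuclear transport, camera gave an adjusted p of 0.000498, and 0.123 with an estimated correlation. MHC class II genes rose in 11 of 16 cases and fell in 2 (13 and 2 adjusted over the list alone), with HLA-DMB at 1.27 ± 0.10 and HLA-DOB, which overlaps another gene, at 1.71 ± 0.13. For MHC class II, camera gave an adjusted p of 0.000214, and 0.134 with an estimated correlation. Interferon-stimulated genes rose in 13 of 31 cases and fell in 7 (15 and 7 adjusted over the list alone), with OAS1 at 2.89 ± 0.15 and OAS3 at -1.06 ± 0.16. For interferon-stimulated genes, camera gave an adjusted p of 0.0185, and 0.0588 with an estimated correlation.

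Among genes of B-cell lymphoma fixed in advance, BCL2 (0.71 ± 0.09) and MCL1 (0.60 ± 0.09) rose and IRF4 fell (-0.99 ± 0.08) in OCI-LY3. BCL6 (-0.16 ± 0.08, adjusted p = 0.137), NFKBIA (0.01 ± 0.14, 0.998) and PRDM1 (0.04 ± 0.13, 0.846) did not pass edgeR's test, but BCL6 did with total counts (-0.27, edgeR adjusted p = 0.0142) and with GC and length offsets (-0.22, 0.0157). Neither did MYC (-0.95 ± 1.06, edgeR adjusted p = 0.511), whose replicates disagreed. MYC was at 18.1, 164 and 161 CPM in the untreated and at 12.7, 152 and 11.9 CPM in the treated OCI-LY3 libraries, and without the second treated library its log2 fold change was -3.22 with an edgeR adjusted p of 0.0238. In all, 7321 of 16474 tested genes were called in OCI-LY3, 3664 higher and 3657 lower in treated cells (edgeR quasi-likelihood, adjusted p under 0.05), and 2958 of them had an absolute log2 fold change of at least 1. With total counts in place of TMM factors, 2939 were higher and 4388 lower in OCI-LY3.

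In SU-DHL6, CDT1 had the largest fall and ARRDC3 the largest rise among the genes with a mean log2 CPM of at least 3 there, chosen by the same rule. CDT1 (ENSG00000167513, chromosome 16, 88803213 to 88809258) went from 505.5 ± 86.3 to 8.84 ± 0.64 CPM (SD, n = 3), a log2 fold change of -5.84 ± 0.16 (SE). E2F2 (-5.14 ± 0.13), the thymidine kinase gene TK1 (-4.64 ± 0.13), CDC45 (-4.51 ± 0.15), ORC1 (-4.02 ± 0.11) and DTL (-3.81 ± 0.13), genes of DNA synthesis or its control, also fell. The kinesin gene KIF21B (-4.39 ± 0.18) fell, as did the ATF4 target CHAC1 (-5.32 ± 0.36), whose counts differed more than 2-fold between replicates of a group. ARRDC3, an arrestin family gene, rose by 3.84 ± 0.15, the synaptic scaffold gene PCLO by 3.77 ± 0.36, the transporter genes SLC16A9 by 3.05 ± 0.16 and SLC16A14 by 2.72 ± 0.13, and ZNF441 by 2.73 ± 0.26. The signal recognition particle RNAs RN7SL1 (3.18 ± 0.72) and RN7SL2 (2.998 ± 0.68), which are near-identical, and LRRC8D (2.74 ± 0.37), which overlaps another gene, also rose, but their counts differed more than 2-fold between replicates. With the libraries of SU-DHL6 alone, the RN7SL1 call was lost (edgeR adjusted p = 0.0555).

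Of the 48 DNA replication and E2F target genes 47 fell and 0 rose in SU-DHL6 (48 and 0 adjusted over the list alone), with a median of -2.49. Of the 48 mitosis genes 40 fell and 1 rose (the same adjusted over the list alone), with ESPL1 at -2.44 ± 0.10 and KIF2C at -2.36 ± 0.10. Camera gave adjusted p values of 2.4e-38 and 6.6e-16, and of 0.000107 and 0.0344 with an estimated correlation. The mitosis gene that rose, HMMR (0.46 ± 0.14), lost its call with GC and length offsets and without the second untreated or the second treated library (edgeR adjusted p = 0.193, 0.0775 and 0.0927). DNA repair genes fell in 24 of 41 cases and rose in 6 (27 and 6 adjusted over the list alone), with RAD54L at -3.75 ± 0.12 among the falls and ATR at 1.35 ± 0.20 among the rises. For DNA repair, camera gave an adjusted p of 1.6e-06, and 0.137 with an estimated correlation, and total counts moved the median from -0.74 to -0.47. Replication histone genes rose in 11 of 23 cases and fell in 1 (13 and 2 adjusted over the list alone), with HIST1H2BD at 2.14 ± 0.18 and HIST1H4I at 1.46 ± 0.16. For replication histones, camera gave an adjusted p of 0.00541, and 0.0355 with an estimated correlation.

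ATF4 target genes fell in 31 of 33 cases and rose in 0 (the same adjusted over the list alone), with PSAT1 at -3.38 ± 0.10 and AARS at -1.93 ± 0.08. For ATF4 targets, camera gave an adjusted p of 2.5e-22, and 0.00233 with an estimated correlation. Fatty acid synthesis genes fell in 9 of 14 cases and rose in 2 (the same adjusted over the list alone), with FADS1 at -1.42 ± 0.10 and SCD at -1.10 ± 0.08. ACSL4, 1 of those that rose (0.30 ± 0.11, edgeR adjusted p = 0.0479), lost its call in 9 of 18 alternatives, among them GC and length offsets (-0.0031, edgeR adjusted p = 0.997) and leaving out any SU-DHL6 library but the first untreated one (edgeR adjusted p = 0.0623 to 0.215). For fatty acid synthesis, camera gave an adjusted p of 0.00223, and 0.0308 with an estimated correlation, and total counts moved the median from -0.55 to -0.28. Cholesterol synthesis genes fell in 10 of 25 cases and rose in 1 (the same adjusted over the list alone), with FDPS at -1.14 ± 0.10 and INSIG1 at -0.94 ± 0.08. For cholesterol synthesis, camera gave an adjusted p of 0.0156, and 0.0572 with an estimated correlation. The list's median of -0.26 became 0.01 when libraries were scaled by total counts. That scaling also moved the median over all genes, from 0.00 to 0.27, and camera was not run with it. The value of 0.01 therefore does not show that the list's fall relative to other genes was lost. Heat shock genes rose in 14 of 20 cases and fell in 1 (15 and 1 adjusted over the list alone), with the chaperone genes HSPH1 at 1.87 ± 0.11 and DNAJA1 at 1.84 ± 0.11 and with HSF1, their transcription factor, at -0.98 ± 0.18. For heat shock genes, camera gave an adjusted p of 7.3e-07, and 0.00449 with an estimated correlation. Oxidative phosphorylation genes fell in 14 of 40 cases and rose in 1 (the same adjusted over the list alone), with SDHA at -1.17 ± 0.10 and UQCRC1 at -0.93 ± 0.08. The oxidative phosphorylation call (camera adjusted p = 0.0123) was lost with an estimated correlation (adjusted p = 0.488), and scaling by total counts turned the median from -0.19 to 0.07. That turn, too, went with the move of the median over all genes.

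Cytosolic ribosomal protein genes fell in 52 of 61 cases and rose in 0 in SU-DHL6 (54 and 0 adjusted over the list alone), with a median of -0.81, RPL3 at -1.78 ± 0.12 and RPL12 at -1.55 ± 0.12. Camera called the list (adjusted p = 8.1e-16), but not with an estimated correlation (adjusted p = 0.149). The share of counts on pseudogenes moved with it, from 7.69 to 8.41% in untreated to 5.13 to 6.05% in treated libraries, and the count-weighted GC content went from 49.7 to 50.7% to 48.9 to 49.3%. Ribosome biogenesis genes rose in 27 of 43 cases and fell in 5 (29 and 5 adjusted over the list alone), with NOP58 at 0.99 ± 0.10 and GNL3 at 0.97 ± 0.10. For ribosome biogenesis, camera gave an adjusted p of 1.5e-06, and 0.00765 with an estimated correlation. NF-kB target genes fell in 23 of 38 cases and rose in 1 (23 and 2 adjusted over the list alone), with LTA at -1.80 ± 0.11 and CCL3 at -2.58 ± 0.23. For NF-kB, camera gave an adjusted p of 0.000113, and 0.0604 with an estimated correlation. Germinal centre genes fell in 13 of 25 cases and rose in 3 (the same adjusted over the list alone), with ASB13 at -1.29 ± 0.09 and EZH2 at -1.19 ± 0.11. For germinal centre genes, camera gave an adjusted p of 0.00241, and 0.0294 with an estimated correlation. Interferon-stimulated genes rose in 8 of 31 cases and fell in 2 (7 and 2 adjusted over the list alone), with IRF7 at 1.07 ± 0.12 and OAS2 at 0.93 ± 0.12. For interferon-stimulated genes, camera gave an adjusted p of 0.0170, and 0.0572 with an estimated correlation. Scaling by total counts moved the median of the ribosome biogenesis list from 0.39 to 0.66, of the NF-kB list from -0.51 to -0.24 and of the germinal centre list from -0.42 to -0.16. The median over all genes moved with them, from 0.00 to 0.27.

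Of the genes fixed in advance, BCL2 rose (0.79 ± 0.09) and CDKN1A (-2.77 ± 0.12), MCL1 (-0.40 ± 0.09), NFKBIA (-0.71 ± 0.14) and IRF4 (-0.51 ± 0.08) fell in SU-DHL6. The MCL1 call was lost when libraries were scaled by total counts (log2 fold change -0.14, edgeR adjusted p = 0.239). BCL6 (-0.13 ± 0.08), MYC (0.47 ± 1.17) and PRDM1 (-0.86 ± 0.38) did not pass edgeR's test (adjusted p = 0.215, 0.790 and 0.265). PRDM1 was near the floor of this depth, at 0.268 CPM untreated and 0.144 CPM treated. In all, 7123 genes were called in SU-DHL6, 3365 higher and 3758 lower in treated cells, and 2633 of them had an absolute log2 fold change of at least 1. The split depended on scaling: with total counts in place of TMM factors, which were 0.974 to 1.04 in untreated and 1.17 to 1.23 in treated libraries, 5451 genes were higher and 2367 lower, and the median over all genes moved from 0.00 to 0.27.

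**Figure D2:**
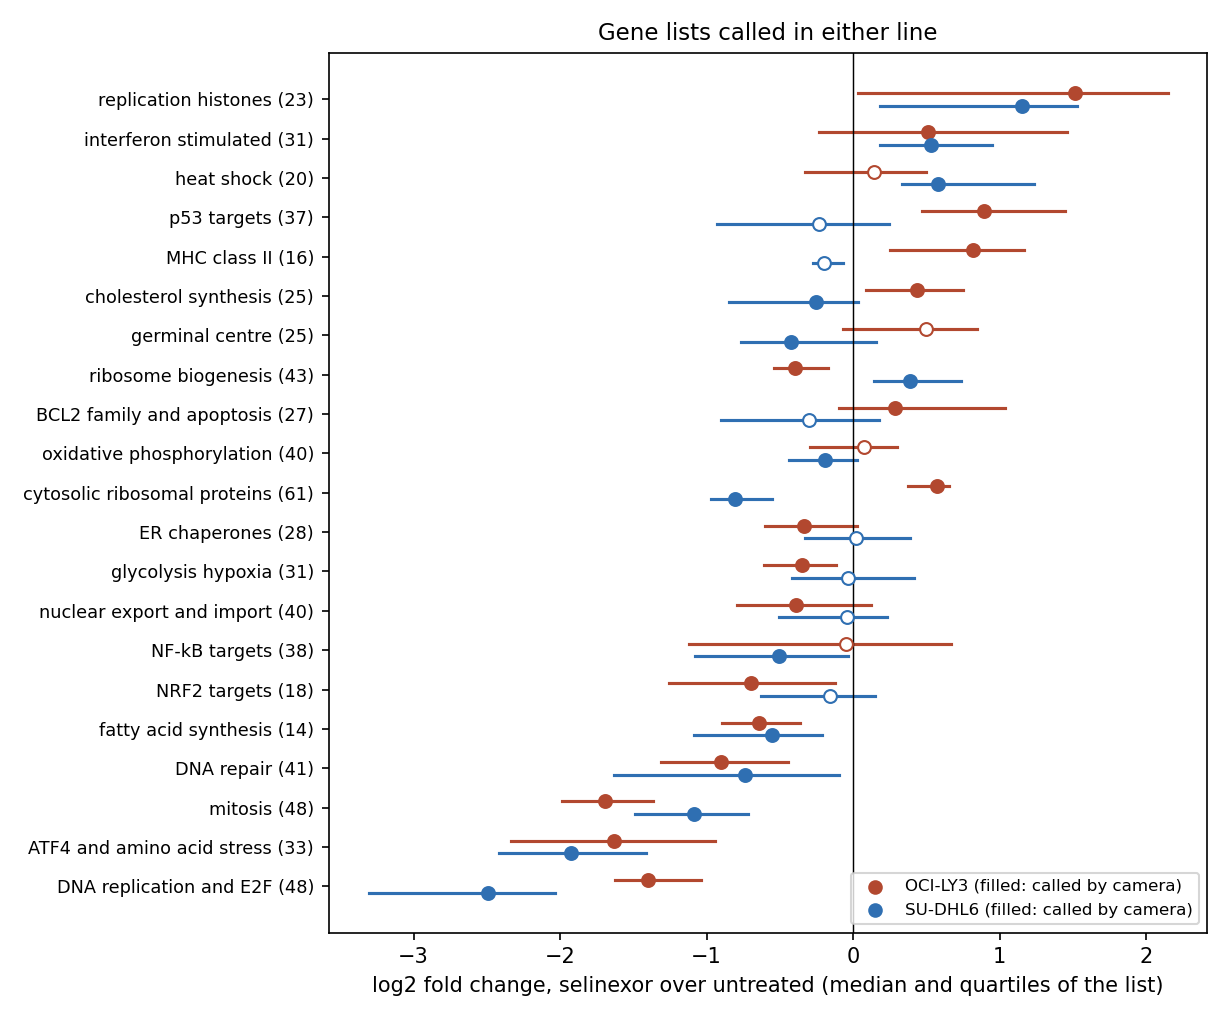
Median log2 fold change (selinexor over untreated) of the members of each gene list called in either line, with quartiles as lines, the number of measured members in brackets, red for OCI-LY3 and blue for SU-DHL6. Filled points were called by camera with the preset correlation; the DNA replication, mitosis and ATF4 lists had negative medians in both lines, and the cytosolic ribosomal protein list had medians of 0.57 in OCI-LY3 and -0.81 in SU-DHL6.

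The responses of the lines were compared directly through the interaction term, and 6072 genes differed, 2798 with a more positive response in SU-DHL6 and 3274 with a more negative one (edgeR quasi-likelihood, adjusted p under 0.05). With total counts in place of TMM factors 4891 were more positive and 1817 more negative, and the median over all genes was 0.35. KCNJ11 (ENSG00000187486, chromosome 11, 17385859 to 17389331) rose by 4.08 ± 0.48 in OCI-LY3 and had a log2 fold change of -1.91 ± 0.46 in SU-DHL6, a difference of -5.99 ± 0.66. JCHAIN, the immunoglobulin joining chain gene, rose by 5.91 ± 0.20 in OCI-LY3 and by 0.65 ± 0.12 in SU-DHL6 (difference -5.26 ± 0.24). ID3, an inhibitor of E-protein transcription factors, rose by 2.97 ± 0.13 and fell by 1.5 ± 0.13 (difference -4.46 ± 0.18). KIF21B was at -4.39 ± 0.18 in SU-DHL6 and at -0.14 ± 0.13 in OCI-LY3 (difference -4.25 ± 0.22). In the other direction, BHLHE40, a transcriptional repressor gene, fell by 2.59 ± 0.11 in OCI-LY3 and rose by 0.98 ± 0.10 in SU-DHL6 (difference 3.57 ± 0.15), DUSP15 went by -1.30 ± 0.12 and 2.37 ± 0.14 (difference 3.67 ± 0.18) and ADIRF-AS1, which overlaps another gene, by -1.20 ± 0.15 and 2.63 ± 0.19 (difference 3.83 ± 0.24).

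CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339) went from 219 to 496 CPM in OCI-LY3 and from 62.4 to 9.15 CPM in SU-DHL6, a difference of -3.95 ± 0.16 on the log2 scale (edgeR adjusted p = 4.6e-09). It was higher in 3 of 3 treated OCI-LY3 libraries than in any untreated one, and lower in 3 of 3 treated SU-DHL6 libraries. Of the 37 p53 targets, 26 had a more negative response in SU-DHL6 and 0 a more positive one (30 and 0 adjusted over the list alone). For this list, camera gave an adjusted p of 1.7e-12, and 0.00082 with an estimated correlation. In SU-DHL6 alone 4 p53 targets rose and 16 fell (7 and 16 adjusted over the list alone), a list that camera did not call (adjusted p = 0.0605) and whose median of -0.23 became 0.03 with total counts. The median over all genes in SU-DHL6 moved likewise, from 0.00 to 0.27. The BCL2 family and apoptosis list also had a more negative response in SU-DHL6 in 12 of 27 cases and a more positive one in 2 (13 and 2 adjusted over the list alone), with BCL2L1 at -2.60 ± 0.16, PMAIP1 at -3.04 ± 0.17 and BAX at -2.29 ± 0.17 for the difference. For apoptosis, camera gave an adjusted p of 0.00285, and 0.0276 with an estimated correlation. MT2A (4.32 ± 0.27) and ACTG2 (-4.22 ± 1.00) also differed, but SU-DHL6 held little of either transcript, with MT2A at 0.980 CPM and ACTG2 at 0.155 CPM when untreated, the second of these under the floor. Without the first untreated SU-DHL6 library the ACTG2 call was lost (edgeR adjusted p = 0.0891). ZBED6 (5.26 ± 1.35) overlaps another gene and its counts differed more than 2-fold between replicates.

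Across the 16474 tested genes, the log2 fold changes of the lines correlated at r = 0.232 (Spearman rho = 0.189). This is a correlation across genes, which are not independent replicates. Leaving out single libraries gave 0.192 to 0.220, in fits that filtered genes anew and tested 16871 to 17038 genes. That range therefore does not reflect the libraries alone. The lines share no control library. A total of 981 genes rose in both lines, where independent lists would share 748, and 1454 fell in both, where they would share 834. Of the 3719 genes called in both lines, 65.5% had the same sign, while 729 rose in OCI-LY3 and fell in SU-DHL6 and 555 did the reverse. NGFR rose in both lines, in SU-DHL6 to 89.7 CPM from 0.153 CPM, a level under the floor, so no exact fold is given there. PSAT1 and ASNS fell by nearly equal amounts, with differences between the lines of -0.03 ± 0.13 and 0.04 ± 0.29 (edgeR adjusted p = 0.915 and 0.967).

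**Figure D3:**
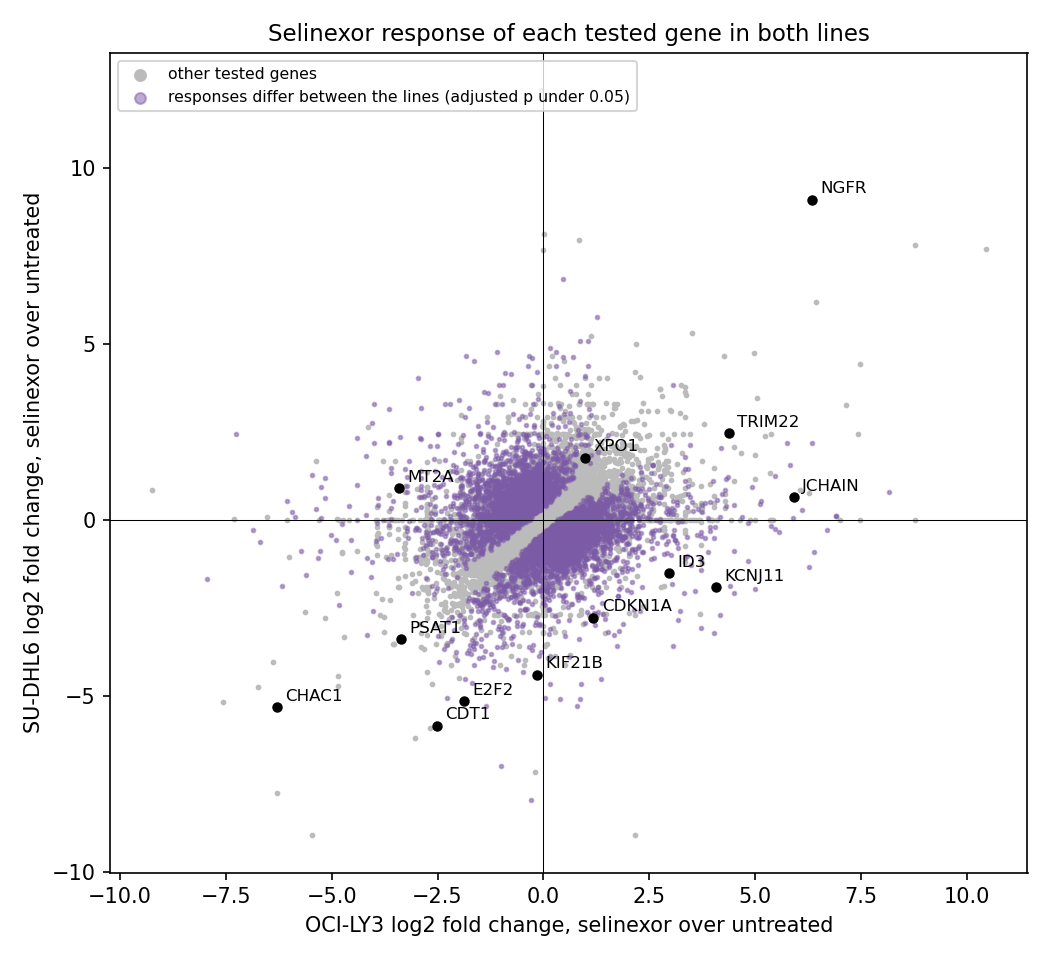
Log2 fold change (selinexor over untreated) of each tested gene in OCI-LY3 (horizontal axis) and SU-DHL6 (vertical axis), with 1 point per gene. Purple points are the 6072 genes whose responses differed and black points are named genes; NGFR and XPO1 lie at upper right, PSAT1 and CHAC1 at lower left, and CDKN1A, KCNJ11 and ID3 rose in OCI-LY3 and fell in SU-DHL6.

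The untreated lines were compared as a reference for these responses; this compares 1 line with another, not the lymphoma types, and the growth protocol names different serum shares for the cultures. Activated B-cell type genes were higher in OCI-LY3 in 22 of 26 cases and lower in 4 (the same adjusted over the list alone), with IRF4 at 895 ± 15.2 against 136 ± 4.09 CPM (log2 difference 2.72 ± 0.08) and the cyclin gene CCND2 at 873 against 0.403 CPM (11.05 ± 0.15). Germinal centre genes were lower in OCI-LY3 in 19 of 25 cases and higher in 6 (the same adjusted over the list alone), with BCL6 at a log2 difference of -0.93 ± 0.08. NF-kB target genes were higher in OCI-LY3 in 27 of 38 cases and lower in 6, and MHC class II genes lower in 12 of 16 and higher in 2 (the same adjusted over the list alone for both). EPHB1, a receptor kinase gene, and MYOCD were at 478 and 362 CPM in OCI-LY3 and had 0 counts in untreated SU-DHL6, so that they were at least 2365-fold and 1792-fold higher. POU3F1 (11.05 ± 0.33) was also higher in OCI-LY3, but was near the floor in untreated SU-DHL6, at 0.211 CPM. IGLL5, which overlaps another gene, and APOD had 0 counts in untreated OCI-LY3 and were at least 3394-fold and 1080-fold lower there, and DTX1, a Notch pathway gene, had a log2 difference of -11.56 ± 0.25. IGKC and FCRL3, with no more than 3 counts in untreated OCI-LY3, were higher in SU-DHL6 by ratios with 95% counting intervals (exact Clopper-Pearson) of 8144 to 242930 and 2771 to 82656, which cover counting error only. In all, 11089 genes differed, 5537 higher and 5552 lower in OCI-LY3 (edgeR quasi-likelihood, adjusted p under 0.05).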

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

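The tests of overlapping genes and of other splits of the libraries were set before their results were seen; the tests of swapped labels, scaling, GC and length, pseudogenes, genes without an overlap and genes at exactly 1 count were chosen only after the results they bear on were seen.

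The selinexor response differed between the lines for 6072 genes by edgeR's test of the difference (SU-DHL6 minus OCI-LY3). Of 212 genes named in a treatment comparison, 142 differed, against 6072 of all 16474 tested genes. Apart from the genes fixed in advance, the 212 were chosen by their response in a line, so their share does not stand for other genes. Among the genes fixed in advance the log2 difference was 0.78 for XPO1, -0.996 for MCL1, -3.95 for CDKN1A, -0.72 for NFKBIA and 0.48 for IRF4. The largest differences among genes that met the naming rule were those of ZBED6 (5.26), MT2A (4.32), ADIRF-AS1 (3.83), DUSP15 (3.67) and BHLHE40 (3.57), and of KCNJ11 (-5.99), JCHAIN (-5.26), ID3 (-4.46), KIF21B (-4.25) and ACTG2 (-4.22). The size for ACTG2 is uncertain, since its level in untreated SU-DHL6 was under the floor. Its difference was -3.09 without the first untreated SU-DHL6 library.

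Camera called a difference for 15 of 32 lists with the preset correlation and for 7 with an estimated correlation. Those called both ways had median log2 differences of -1.11 (p53 targets), -1.25 (DNA replication), -0.75 (apoptosis), 0.73 (ribosome biogenesis), -0.80 (cholesterol synthesis), 0.72 (heat shock) and -0.69 (germinal centre). Those called only with the preset correlation had medians of 0.41 (nuclear transport), 0.56 (mitosis), -1.34 (cytosolic ribosomal proteins) and 0.26 (endoplasmic reticulum list). Others called only this way had medians of -0.37 (B-cell receptor signalling), -0.82 (MHC class II), 0.39 (glycolysis and hypoxia) and -0.28 (oxidative phosphorylation). With an estimated correlation, camera's adjusted p for these 8 was 0.211, 0.220, 0.101, 0.101, 0.141, 0.101, 0.101 and 0.520. With total counts, the medians of the 7 lists called both ways became -0.73, -0.87, -0.38, 1.12, -0.42, 1.08 and -0.32, and those of the other 8 became 0.78, 0.94, -0.96, 0.64, 0.01, -0.45, 0.77 and 0.10, in the same order. The median difference over all genes with total counts was 0.35. With GC and length offsets, the medians of the nuclear transport and B-cell receptor lists became 0.22 and -0.24.

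For the treatment comparisons and the untreated lines, 3 libraries against 3 make 10 splits, too few for a share under 0.05. In OCI-LY3 only 1 of them, the real one, gave 7321 genes, and the highest other gave 2. In SU-DHL6 only 1 gave 7123, against 1 in the highest other, and between the untreated lines only 1 gave 11089, against 2. The real split called 17 lists in OCI-LY3 and 14 in SU-DHL6, and the highest other split 15 and 12. Each other split of a line sets 2 treated and 1 untreated libraries against 1 treated and 2 untreated ones, so part of the response remains. These list counts therefore do not show how many lists would be called without the response. For the difference between the lines, 2 of 100 splits, the real one included, gave at least 6072 genes, but this share does not decide whether chance made the difference. Only 2 of the 100 keep the replicates of each group together. The rest mix treated with untreated libraries in 1 or both lines. This weakens the response where libraries are mixed but does not remove it, and can leave the other line's response whole. The other of the 2, with 7307 genes, exchanges treated and untreated libraries within a line and so tests the sum of the responses; the next gave 2311 and 68 gave 0.

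Different responses of CDKN1A and p53 targets in the lines were weighed against technical explanations. Of the 75 ATF4 and DNA replication genes called in both lines, 100% had the same sign, where exchanged labels in SU-DHL6 would make them opposite. That outcome was fixed before this test was chosen, since these lists had 0 rises in either line. The ribosomal protein genes moved in opposite directions, so the test does not exclude an exchange of treated and untreated labels. Scaling is excluded as the whole cause, since at least 21 p53 targets, against 26 with TMM factors, were lower in the difference under 3 other scalings, with CDKN1A at -3.57 or beyond. GC content and gene length are excluded likewise, with 26 targets lower and CDKN1A at -3.63. A difference between the lines may be biological, but an exchange of labels is not excluded. Dose, time and serum share may also differ between the lines and were not tested.

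Of 61 ribosomal protein genes, 42 rose in OCI-LY3, 52 fell in SU-DHL6 and 55 were lower in the difference, but camera called the list in neither line with an estimated correlation (adjusted p = 0.262 and 0.149). GC content and length are excluded as the whole cause (56 genes lower with offsets), as is scaling (at least 51 genes lower, with a median of -0.96 under total counts). Reads moving between these genes and their 1144 pseudogenes are excluded as the whole cause. The summed pseudogene counts moved the same way as the genes, with a difference of -1.48 ± 0.16 (SE). A smaller part from shared reads is not excluded, since their handling is not stated. Line, dose, time, the different serum shares of the growth protocol and an exchange of labels stay open. For the difference, camera's adjusted p with an estimated correlation was 0.101.

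Counts of 765 tested genes differed more than 2-fold between replicates of a group. Summing overlapping genes brought 273 of the 572 that overlap another gene within 2-fold (47.7%), which leaves reads shared between overlapping genes undecided for them. The other 193 (25.2%), MYC among them, overlap no gene with a count, which excludes such sharing there. A total of 235 genes had exactly 1 count in all 12 libraries, so the deposited values may be rounded estimates, but this does not show that estimation made the differences between replicates. No biological explanation was tested.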

How the results depend on the processing

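Scaling by total counts, GC and length offsets, and fits without overlapping genes or without genes that differed between replicates were chosen only after the results were seen. Of 275 results for named genes, 243 kept their direction and side of the threshold under every alternative run; over 4951 alternatives, 4824 did so, 109 lost the call, 3 gained it and 15 reversed. A log2 fold change of at least 1 left 2958 genes in OCI-LY3, 2633 in SU-DHL6, 3313 in the difference and 6887 between the untreated lines, and an adjusted p under 0.01 left 3941 in the difference, because these thresholds are stricter. With an estimated correlation camera called 9 lists in OCI-LY3 and 8 in SU-DHL6, and fry, which does not compare a list with other genes, called 27 and 27. The correlation between the lines was 0.0775 without the filter on low counts and 0.267 over called genes. It was 0.192 to 0.220 with a library left out and the genes filtered anew. The first component held 96.0% of the variance of the 500 most variable genes.

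Uncalled log2 fold changes near 0 reversed, and the cause was not tested. NFKBIA in OCI-LY3 was at -0.0022 with limma-voom, -0.0063 without the filter, -0.0030 with the replicate block, -0.0071 with that line alone, -0.11 with total counts, -0.058 with GC and length offsets, and -0.10 to 0.15 with a library left out. PRDM1 in OCI-LY3 was at -0.077 with total counts and -0.0083 to 0.089 with a library left out. In SU-DHL6 BCL6 was at 0.13 with total counts. ACSL4 in SU-DHL6, a called rise of 0.30 ± 0.11 (edgeR adjusted p = 0.0479), lost its call in 9 of 18 alternatives, 5 of them with a library left out, and was at -0.0031 with GC and length offsets.

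Same-numbered libraries showed no clear shared deviation, with correlations of 0.01, 0.00 and 0.01 in OCI-LY3 and of -0.12, -0.02 and 0.05 in SU-DHL6. This does not settle whether the cultures were paired, which the labels do not state. With the replicate number as a block 6585, 6360, 5216 and 8620 genes were called in OCI-LY3, SU-DHL6, the difference and the untreated lines. For the untreated lines, that fit compares fitted levels at replicate 1 and not means over replicates. Its 8620 genes are thus not directly comparable with the 11089 of the main fit. Leaving out a library of the groups compared gave 6293 to 6569, 5958 to 7445, 5244 to 6683 and 10455 to 10952. Leaving out a library of the other groups gave 7289 to 7892 in OCI-LY3, 6968 to 7175 in SU-DHL6 and 11153 to 11258 between the untreated lines. Genes under the floor of 3 counts per library are beyond this depth. Most 1.5-fold changes were missed in the simulated counts, but those shares do not carry over to the data.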

Other observations

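No test in this part was chosen after its result was seen. The named genes below come from lists that camera did not call. They are only part of those selected by the rule fixed in advance, and were picked after their values were seen. In OCI-LY3, the immunoglobulin joining chain gene JCHAIN (5.91 ± 0.20) and the BCMA receptor gene TNFRSF17 (2.68 ± 0.24) rose, while the plasma cell list had 5 of 20 genes higher and 6 lower (6 and 7 adjusted over the list alone). For plasma cell genes, camera gave an adjusted p of 0.925. B-cell receptor signalling genes rose in 11 of 32 cases and fell in 4 (the same adjusted over the list alone; camera adjusted p = 0.114), with CD79B at 1.74 ± 0.11. Germinal centre genes rose in 13 of 25 cases and fell in 4 (15 and 4 adjusted over the list alone). For germinal centre genes, camera gave an adjusted p of 0.0983. Autophagy and lysosome genes rose in 12 of 29 cases and fell in 3 (the same adjusted over the list alone). For autophagy and lysosome genes, camera gave an adjusted p of 0.0660. FOXO targets rose in 7 of 22 cases and fell in 3 (the same adjusted over the list alone; camera adjusted p = 0.588), with PIK3IP1 at 1.56 ± 0.16. Known XPO1 cargo genes rose in 7 of 26 cases and fell in 6 (the same adjusted over the list alone). For XPO1 cargo in OCI-LY3, camera gave an adjusted p of 0.845.

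In OCI-LY3 camera likewise did not call NF-kB targets (13 rose and 14 fell of 38, adjusted p = 0.449), heat shock genes (9 and 4 of 20, 0.218) or oxidative phosphorylation genes (7 and 8 of 40, 0.845). Nor did it call activated B-cell type genes (10 and 7 of 26, camera adjusted p = 0.274), MHC class I genes (4 and 8 of 17, 0.196) or mitochondrially encoded genes (1 and 5 of 13, 0.243). Immediate early genes rose in 7 and fell in 8 of 24 cases (camera adjusted p = 0.861), with a median of -0.52, a mean of -0.08 and a test direction of up. Adjusted over the list alone, the numbers for these 7 lists were 13 and 15, 9 and 4, 6 and 5, 10 and 7, 5 and 9, 1 and 5, and 7 and 8.

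In SU-DHL6, the chaperone genes HSP90B1 (2.04 ± 0.11) and HSPA5 (1.31 ± 0.08) rose, but the endoplasmic reticulum list, with 11 of 28 genes higher and 6 lower (the same adjusted over the list alone), was not called (camera adjusted p = 0.516). TXNIP rose by 1.82 ± 0.11, with 4 FOXO targets of 22 higher and 1 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.411). Apoptosis genes fell in 12 of 27 cases and rose in 4 (the same adjusted over the list alone). For apoptosis genes, camera gave an adjusted p of 0.0857. B-cell receptor genes fell in 14 of 32 cases and rose in 7 (the same adjusted over the list alone; camera adjusted p = 0.254), and nuclear transport genes fell in 14 of 40 and rose in 6 (the same adjusted over the list alone). For nuclear transport, camera gave an adjusted p of 0.512. XPO1 cargo genes fell in 9 of 26 cases and rose in 4 (the same adjusted over the list alone; camera adjusted p = 0.411).

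Also not called by camera in SU-DHL6 were MHC class II genes (0 rose and 3 fell of 16, adjusted p = 0.0931), glycolysis and hypoxia genes (9 and 12 of 31, 0.936), NRF2 targets (3 and 7 of 18, 0.160) and activated B-cell type genes (6 and 9 of 26, 0.647). The same held for plasma cell genes (5 and 8 of 20, camera adjusted p = 0.304), MHC class I genes (2 and 4 of 17, 0.304), immediate early genes (4 and 9 of 24, 0.302), autophagy and lysosome genes (6 and 10 of 29, 0.647) and mitochondrially encoded genes (0 and 0 of 13, 0.666). Adjusted over the list alone, the numbers for these 9 lists were 0 and 2, 9 and 14, 3 and 7, 7 and 10, 5 and 9, 2 and 4, 4 and 9, 6 and 10, and 0 and 0. The median of the activated B-cell type list was 0.05 and its mean -0.02.

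Of the markers of other cell types, 6 of 18 T-cell, 5 of 18 myeloid and 4 of 16 epithelial and fibroblast genes were measured. Camera gave adjusted p values of 0.274 and 0.941 for the T-cell list and 0.818 and 0.647 for the myeloid list in OCI-LY3 and SU-DHL6, and the epithelial and fibroblast list was too short to test. Among T-cell markers 3 rose and 1 fell in OCI-LY3 and 2 rose and 2 fell in SU-DHL6. Among myeloid markers 2 rose and 2 fell in OCI-LY3 and 1 rose and 0 fell in SU-DHL6, and among epithelial and fibroblast markers 1 rose and 2 fell in OCI-LY3 and 0 rose and 0 fell in SU-DHL6. Adjusted over the list alone these numbers were the same, except for 0 and 0 myeloid markers in SU-DHL6 and 1 and 3 epithelial and fibroblast markers in OCI-LY3. The myeloid marker that rose in SU-DHL6, AIF1, lost its call in 5 of 18 alternatives. Among the other markers, calls were lost in 5 of 18 for CD5, 7 of 18 for COL1A1 and 3 of 18 for FN1 in OCI-LY3, and in 4 of 17 for CD8A and 3 of 17 for CD3E in SU-DHL6. The mitochondrial share of counts was 9.27 to 9.76% in untreated and 7.62 to 8.32% in treated OCI-LY3, and 7.83 to 7.998% in untreated and 8.86 to 10.7% in treated SU-DHL6.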
